A study of Mus musculus with 15 samples.

How the data were processed

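RNA-seq libraries of polyadenylated RNA were analysed from the mouse embryonic stem cell line E14TG2, per the labels: 3 libraries each of ESCs at day 0, of control and Atg7 KO cells at day 2, and of control and Atg7 KO cells at day 4 of the transition to EpiLCs. Each sample's group and replicate number came from its title. Per the labels' protocols, ESCs were kept on inactivated mouse embryonic fibroblasts and were seeded on fibronectin for the transition.

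The values used were raw counts of reads per gene symbol as deposited by the authors, 1 table per library. Per the submitters' processing notes, STAR, featureCounts, StringTie and DESeq2 were used with the builds mm10 and GRCm38. Their versions, settings, the annotation, strandedness and the treatment of reads shared between genes are not given in the sources used here. Near-identical copies such as the Zscan4, Usp17l and replication-dependent histone genes, and overlapping or antisense genes, are therefore uncertain. Of the symbols, 3371 had 0 counts in every library. Totals lay between 14059237 and 23371546 counts, and the 10 most abundant genes took between 4.2% and 5.74% of a library. No pair of libraries in a group differed by as little as sampling noise, with chi-square per degree of freedom between 3.2 and 31.78 for genes with at least 20 counts, so each library was counted as 1 sample.

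Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 5 groups with a minimum count of 10 and a minimum total of 15, which left 15696 genes and removed 9286. Libraries were scaled with TMM factors, and 1 quasi-likelihood model with a mean per group was fitted to all 15 libraries. The comparisons were control day 2 against ESCs, control day 4 against control day 2, control day 4 against ESCs, KO against control at each day, KO day 4 against KO day 2, and the difference of the KO effect between the days. P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, with a threshold of 0.05 and no fold minimum. Levels are CPM with TMM-scaled library sizes. A fold change against a group with 0 counts was computed against 3 counts over the group, which covers counting error only.

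Before the data were examined, 32 gene lists, the tests, the alternatives and the rule for the genes to name were fixed. The lists were tested with limma 3.58.1's camera on voom values with an inter-gene correlation preset at 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and 31 of 32 had tested members. The mitochondrially encoded list had 0 tested members. The genes named are Atg7, the 6 largest increases and decreases of a comparison among genes past the test with a mean of at least 5 CPM in the higher group and no overlap between groups (overlap was ignored for the difference between days), any member of the pluripotency and autophagy lists, and up to 2 risen and 2 fallen members of each other list with the smallest p. Symbols of unnamed or predicted genes and of microRNA or snoRNA hosts were left out of the largest changes, and of the genes the rule allows only some are named. Members named where a count was 5 or fewer, and Atf4, Hprt, Vegfa and the values of a named gene in further comparisons, were chosen after their values were seen. The coordinates printed for single genes are from GENCODE M21 on GRCm38. Chromosomes of genes and the positions used for the windows are from RefSeq, in which 98.2% of the tested symbols were found.

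The procedure was tested on simulated data, with counts drawn from the means of the real libraries and 1.5-, 2- and 4-fold changes planted. For KO against control at day 2, 53.7%, 82.8% and 100% of the changed genes were recovered, with 11 calls among 15095 unchanged genes. For day 4 the shares were 45.3%, 78.5% and 100%, with 7 calls among 15104, and for control day 4 against ESCs 61.5%, 92.4% and 95.4%, with 8 among 15128. A shifted set of 20 genes was recovered by camera in each of the 3, and 0, 1 and 0 of 100 unchanged sets had p under 0.05. The genes were drawn independently of one another, so this does not show how camera behaves for lists whose genes vary together. Far fewer genes were changed than passed the test in the real comparisons.

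The alternatives tried were RLE and upper quartile scaling, no filter and a stricter filter (at least 10 CPM in at least 3 libraries), DESeq2 1.42.0, fits of only the groups compared, the replicate number as a block, a test against a 1.5-fold change, an estimated inter-gene correlation, time-course sets without a fold minimum, and leaving out each library in turn. Added after the data were seen were a feeder score (the mean log2 CPM of 3 collagen genes) as a covariate, the main fit with chromosome 18 genes dropped before the adjustment, and a fit of 13 libraries without ESC replicate 3 and KO day 2 replicate 2. Their feeder scores were the lowest (5.86) and the highest (7.49) of their groups. By chi-square KO day 2 replicate 2 did not stand apart from replicate 3 (3.44).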

Results

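Gene expression was measured by RNA-seq of polyadenylated RNA in the mouse embryonic stem cell line E14TG2 during its transition from embryonic stem cells (ESCs) to epiblast-like cells (EpiLCs). ESCs in medium with LIF and 2 kinase inhibitors resemble the naive epiblast before implantation. EpiLCs, obtained here with activin A and bFGF, resemble the epiblast about the time of implantation. The 15 libraries fell into 5 groups of 3: ESCs at day 0, control cells at day 2, Atg7 knockout (KO) cells at day 2, control cells at day 4 and Atg7 KO cells at day 4. No Atg7 KO library of day 0 was analysed here. Total counts were between 14059237 and 23371546 per library, and 15696 genes had enough counts to be tested while 9286 had not. Below, levels are CPM (counts scaled to the same library total) as mean ± SD over the 3 libraries of a group. Fold changes are log2 values ± standard error from the edgeR model fitted to all 15 libraries. Each compares 3 with 3 libraries, except the difference of the KO effect between days, which uses the control and KO groups of both. The standard error draws on the scatter in all groups, so it is not the spread of the compared libraries alone. A gene is said to rise, fall or change only where edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p under 0.05. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

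Atg7 itself checks the labels. The gene (ENSMUSG00000030314.16) lies on chromosome 6 at 114643097 to 114860614, plus strand, in GRCm38, and encodes the E1-like enzyme that conjugates ATG8 proteins to lipid and ATG12 to ATG5, steps that autophagosome formation needs. Its level was 17.6 ± 1.03 CPM in ESCs. At day 2 it was 13.6 ± 1.27 CPM in control and 7.16 ± 0.349 CPM in KO, and at day 4 it was 19.5 ± 0.379 CPM in control and 11.9 ± 1.28 CPM in KO. Every KO library lay below every control library of its day. Atg7 fell by 0.92 ± 0.11 at day 2 (edgeR adjusted p = 8.34e-06) and by 0.71 ± 0.11 at day 4 (edgeR adjusted p = 8.39e-05). The transcript was lowered, not removed. Counts over a whole gene include exons outside any deletion, and which exons were targeted is not given in the sources used here.

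The time course began with ESCs at day 0, whose labels do not call them control, and went on with control cells at day 2 and day 4. Hprt was 195 ± 11.2 CPM in the ESCs and 2.34 ± 0.152 CPM in control at day 2, so whether the ESCs were of the control line is open. Most naive pluripotency genes fell. Nanog, a homeodomain factor of the naive state on chromosome 6 at 122707489 to 122714633, went from 1220 ± 188 CPM in ESCs to 534 ± 35.8 CPM at day 2 and 413 ± 4.27 CPM at day 4. Klf4, a Krüppel-like factor of the same state, went from 579 ± 65.4 to 120 ± 2.85 and 43.0 ± 2.54 CPM. Tfcp2l1, a LIF-responsive factor, went from 1150 ± 61.0 to 327 ± 21.5 and 167 ± 7.34 CPM. From day 0 to day 4, 16 of the 20 genes of the naive list fell, 3 rose (Zfp42, Dppa3 and Fbxo15) and 1 (Klf5) did not pass. Without ESC replicate 3, Klf5 was lower, at -0.23. Of the 3 that rose, Fbxo15, at 0.43, lies on chromosome 18, whose genes had a median of 0.32 in this comparison. Dppa3, at 1.15, lies on chromosome 6, whose genes had a median of 0.44. The counts adjusted over the list alone were 16 fallen and 3 risen. As a set the list was lower by limma's camera test (Benjamini-Hochberg adjusted p = 1.64e-05; adjusted p = 0.0836 with an estimated correlation). Of the general pluripotency genes, Pou5f1, the gene of OCT4, fell by 1.32 ± 0.05 and Sox2 by 1.18 ± 0.06 over the 4 days, and of the 16 members 8 fell and 5 rose (8 and 5 adjusted over the list alone; camera adjusted p = 0.273).

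Genes of the formative and primed states mostly rose. Dnmt3a, a de novo DNA methyltransferase, went from 69.8 ± 9.72 CPM in ESCs to 202 ± 4.57 CPM at day 2 and 487 ± 8.20 CPM at day 4. Otx2, a homeobox factor of the EpiLC programme, was 12.1 ± 1.86, 8.59 ± 0.227 and 29.0 ± 6.44 CPM. Pou3f1, which encodes OCT6, was 3.77 ± 1.31, 6.35 ± 0.8 and 11.1 ± 3.25 CPM. Over the 4 days Otx2 rose by 1.26 ± 0.16 and Pou3f1 by 1.55 ± 0.24. Fgf5, widely used as an EpiLC marker, was low throughout, at 0.380 ± 0.171, 0.0343 ± 0.0301 and 0.640 ± 0.308 CPM. It fell by 3.30 ± 0.84 up to day 2 (edgeR adjusted p = 0.0022) and rose by 4.02 ± 0.76 from day 2 to day 4 (edgeR adjusted p = 0.000175), and its change of 0.72 ± 0.52 over the 4 days did not pass (edgeR adjusted p = 0.223). Of the 19 genes of this list 12 rose and 2 fell from day 0 to day 4 (Zic2 and Tead2), with 12 and 2 adjusted over the list alone (camera adjusted p = 0.0319; adjusted p = 0.285 with an estimated correlation). The set did not pass with a stricter filter (0.128) or without the genes of chromosome 18 (0.0636).

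All 11 tested genes of the 2-cell-like list, which mark a rare state with features of the 2-cell embryo, rose from day 0 to day 4 (11 adjusted over the list alone; camera adjusted p = 2.29e-05; adjusted p = 0.317 with an estimated correlation, and 0.0945 with a collagen score as a covariate, described below). Zfp352, a zinc finger gene of that list on chromosome 4 at 90218820 to 90225702, was 0.726 ± 0.155 CPM at day 2 and 37.2 ± 2.96 CPM at day 4. All 16 germline genes that DNA methylation normally silences rose over the 4 days, among them Sycp3, a synaptonemal complex gene, by 3.46 ± 0.11 (16 adjusted over the list alone; camera adjusted p = 2.54e-08; adjusted p = 0.249 with an estimated correlation). Endoderm genes rose in 15 of 16 cases, with Gata6, a factor of primitive endoderm, higher by 4.49 ± 0.20. The exception was Sparc, at -0.54 ± 0.07 (15 and 1 adjusted over the list alone; camera adjusted p = 1.18e-05; adjusted p = 0.249 with an estimated correlation). Of 20 genes of the integrated stress response, which are mostly induced through ATF4, 17 fell and 1 rose (Ddit4), and Nupr1 was lower by 3.82 ± 0.18 (17 and 1 adjusted over the list alone; camera adjusted p = 9.37e-06; adjusted p = 0.317 with an estimated correlation). Egr1, an immediate early gene, went from 315 ± 123 CPM in ESCs to 0.821 ± 0.386 CPM at day 2. Timd2 had 0 counts in the ESC libraries and 11.4 ± 0.907 CPM at day 2, which was at least 170-fold higher against 3 counts over the group.

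Between ESCs and control at day 4, 11257 of 15696 genes changed, 5676 higher and 5581 lower. From day 0 to day 2, 11072 genes changed (5589 higher and 5483 lower), and from day 2 to day 4, 10741 (5317 higher and 5424 lower). With a test against a 1.5-fold change these counts were 5792, 5273 and 4794. The ESC libraries held unequal amounts of collagen RNA, with Col1a1 at 292 ± 210 CPM in ESCs, 85.8 ± 5.93 CPM in control at day 2 and 12.1 ± 0.999 CPM at day 4. The labels' protocols say that the ESCs were kept on mouse embryonic fibroblasts. With a score of 3 collagen genes as a covariate, chosen after the data were seen, the count for day 4 against day 0 was 7113.

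**Figure D1:**
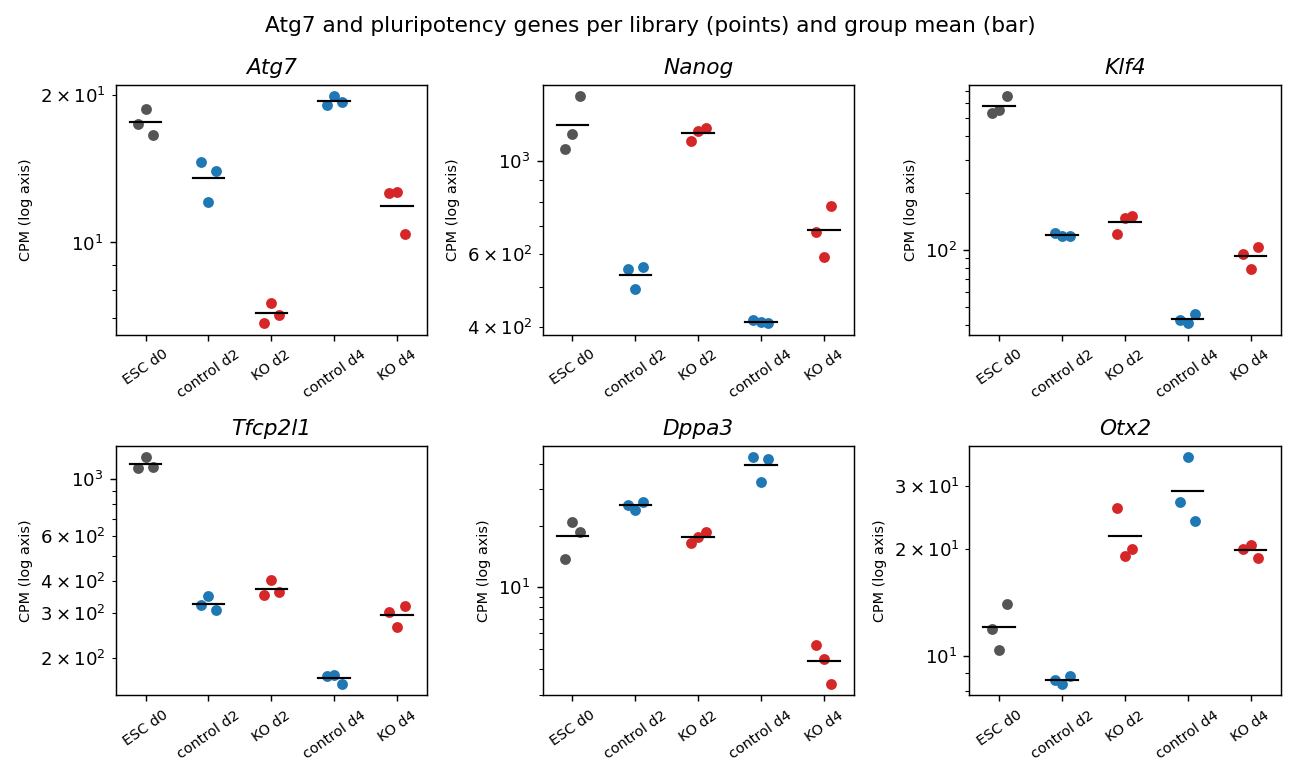
CPM on a log axis of Atg7 and 5 pluripotency genes in each of the 15 libraries (points), with the mean of each group (bar), control in blue and Atg7 KO in red. Nanog was 1170 ± 40.3 CPM in KO and 534 ± 35.8 CPM in control at day 2, and Dppa3 was 4.37 ± 0.921 CPM in KO and 39.2 ± 5.79 CPM in control at day 4.

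The study's title names Atg7-dependent autophagy and Nanog in the exit from the naive state, so KO and control were next compared at day 2. Nanog was 1170 ± 40.3 CPM in KO and 534 ± 35.8 CPM in control, higher by 1.13 ± 0.10 (edgeR adjusted p = 5.08e-07), while ESCs had 1220 ± 188 CPM. Klf2, another Krüppel-like factor of the naive state, was 96.7 ± 11.4 CPM in KO and 52.7 ± 8.49 CPM in control, and Prdm14, which represses FGF signalling and DNA methylation in naive cells, was 44.4 ± 1.34 and 21.6 ± 1.29 CPM. Spic, an ETS factor on chromosome 10 at 88674772 to 88685015, rose the most among these, from 1.85 ± 0.265 CPM in control to 16.9 ± 1.62 CPM in KO. Klf4, at 0.23 ± 0.10 (edgeR adjusted p = 0.0799; 0.32 and past the test without KO replicate 1), and Esrrb, at -0.03 ± 0.07 (edgeR adjusted p = 0.799), did not pass. Of the 20 naive genes 11 rose and 3 fell (Klf5, Dppa3 and Zfp57), with 12 and 4 adjusted over the list alone. The decrease of Klf5 did not pass without any 1 of the control replicates or without KO replicate 1 or 2, where it was between -0.38 and -0.27. As a set they were higher (camera adjusted p = 0.0114; adjusted p = 0.277 with an estimated correlation).

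Formative genes were lower in KO at day 2 in 9 of 19 cases and higher in 2 (Otx2 and Sall2), with 9 and 2 adjusted over the list alone, and the set did not pass (camera adjusted p = 0.117). Pou3f1 was 2.07 ± 0.291 CPM in KO and 6.35 ± 0.8 CPM in control, and Dusp6, a phosphatase induced by ERK, was 19.7 ± 0.797 and 39.4 ± 0.917 CPM. Sall2 did not pass without control replicate 2, at 0.46. Otx2 went the other way, at 21.7 ± 3.77 CPM in KO and 8.59 ± 0.227 CPM in control. Dnmt3a fell by 0.33 ± 0.08 and Dnmt3b by 0.78 ± 0.20. In the general pluripotency list 5 genes rose (Sox2, Sall4, Gdf3, L1td1 and Zfp281) and 7 of 16 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.262, and 0.0162 with the collagen score). Utf1, a chromatin-bound factor of pluripotent cells, fell by 1.45 ± 0.16, and Pou5f1, at -0.02 ± 0.05, did not pass. The rise of Sox2 was 0.15 ± 0.05, and it did not pass without control replicate 1 or 2 or without KO replicate 1 or 3, where it was between 0.12 and 0.16. Zfp281, at 0.18 ± 0.06, did not pass without KO replicate 1 or 3 or without any 1 of the control replicates, where it was between 0.17 and 0.19.

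Autophagy genes other than Atg7 did not move together at day 2. Of 28 genes of the core machinery 9 rose and 6 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.262). Atg12, the ubiquitin-like partner that ATG7 activates, rose by 0.63 ± 0.06, but it lies on chromosome 18, whose genes had a median of 0.56. Map1lc3a, one of the LC3 genes, fell by 0.99 ± 0.19. Of 15 genes of selective autophagy receptors 5 rose (Sqstm1, Nbr1, Tax1bp1, Bnip3l and Wdfy3) and 2 fell (Fkbp8 and Phb2), with 5 and 2 adjusted over the list alone (camera adjusted p = 0.262). Sqstm1, which encodes the receptor p62, was 203 ± 3.61 CPM in KO and 172 ± 7.05 CPM in control. Tax1bp1 rose by 0.66 ± 0.06 and Nbr1 by 0.36 ± 0.05. When 1 library was left out, Bnip3l did not pass in 4 of 6 refits (0.25 to 0.27), Wdfy3 in 5 (0.18 to 0.22) and Phb2 in 5 (-0.18 to -0.14).

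Genes of the G2 and M phases were higher in KO at day 2 in 20 of 24 cases and lower in 0, with 20 and 0 adjusted over the list alone (camera adjusted p = 7.04e-10; adjusted p = 0.277 with an estimated correlation). Kif11, a spindle kinesin, was 186 ± 12.2 CPM in KO and 97.8 ± 5.07 CPM in control. Genes of the S phase fell in 13 of 22 cases and rose in 0, with 13 and 0 adjusted over the list alone (camera adjusted p = 0.00027; adjusted p = 0.415 with an estimated correlation). Ung, a uracil DNA glycosylase, fell by 0.60 ± 0.06. Cholesterol biosynthesis genes fell in 13 of 20 cases and rose in 0, with 14 and 0 adjusted over the list alone (camera adjusted p = 1.86e-05; adjusted p = 0.277 with an estimated correlation). Glycolysis genes fell in 10 of 19 cases and rose in 0, with 10 and 0 adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.708 with an estimated correlation). Pgam1, a phosphoglycerate mutase, fell by 0.62 ± 0.07.

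The 2-cell-like genes were lower in KO at day 2 in 9 of 11 cases, with 9 adjusted over the list alone, and Tmem92 and Sp110 did not pass (camera adjusted p = 0.000518; adjusted p = 0.592 with an estimated correlation). Zscan4f, of a gene cluster that marks this state, was 1.30 ± 0.627 CPM in KO and 8.05 ± 1.32 CPM in control. Zscan4 and Usp17l genes have near-identical copies, so how their reads were shared out is uncertain. Trophoblast genes fell in 7 of 10 cases and rose in 2 (Tfap2c and Tfap2a), with 7 and 2 adjusted over the list alone (camera adjusted p = 0.0332; adjusted p = 0.277 with an estimated correlation). Hand1, a bHLH factor of trophoblast and mesoderm, fell by 3.11 ± 0.43. With a stricter filter the trophoblast set did not pass (0.0794), nor did it with the collagen score (0.0588). Germline genes fell in 6 of 16 cases and rose in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.0466; adjusted p = 0.708 with an estimated correlation), a call also lost without control replicate 1 (mean -0.28) or 3 (-0.28), without KO replicate 1 (-0.29), with a stricter filter (-0.29), without chromosome 18 (-0.30) and with the collagen score (-0.08). Targets of p53 fell in 8 of 19 cases and rose in 0 (8 and 0 adjusted over the list alone; camera adjusted p = 0.0114; adjusted p = 0.708 with an estimated correlation). Genes of the integrated stress response rose in 12 of 20 cases and Cebpb alone fell, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.0307; adjusted p = 0.708 with an estimated correlation). The call of this list was lost without control replicate 3 (camera adjusted p = 0.051), and with the collagen score those of this list (0.139) and of the p53 targets (0.8) were lost. Nupr1, a stress-induced nuclear protein gene, rose by 1.58 ± 0.17 and Chac1, which degrades glutathione, by 1.80 ± 0.29.

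Outside these groups, Lefty1, an inhibitor and target of Nodal, rose at day 2 from 10.2 ± 2.79 CPM in control to 51.2 ± 14.6 CPM in KO. Glcci1 rose by 2.47 ± 0.23, and Sall3 and Cidea, both on chromosome 18, by 2.40 ± 0.21 and 2.27 ± 0.22. The genes of chromosome 18 were higher in KO as a whole, with a median log2 fold change of 0.56 over 401 genes, while the medians of the other autosomes were between -0.08 and 0.09. The 605 genes of the X chromosome had a median of -0.1. On the Y chromosome 7 of the 8 tested genes were higher and 1 was lower, with a median of 0.8. Among the largest decreases were those of Cdcp1, a membrane protein gene, by 2.52 ± 0.25, Esrp1, which encodes a splicing factor, by 2.37 ± 0.28, and Galnt3, a glycosyltransferase gene, by 2.36 ± 0.22. Epcam, an adhesion gene of the general pluripotency list, was 107 ± 3.88 CPM in KO and 210 ± 6.76 CPM in control. Among the genes that the rule for naming allows, the matrix protease gene Mmp3 had the largest increase, 4.55 ± 1.39. It went from 0.249 ± 0.107 CPM in control to 5.78 ± 5.68 CPM in KO. It did not pass without KO replicate 2 (3.50) or without control replicate 2 (4.68) or 3 (4.22). Col1a1, a fibroblast collagen, was also higher in KO, at 202 ± 58.8 CPM against 85.8 ± 5.93 CPM, and without KO replicate 2 its log2 difference was 0.98 (edgeR adjusted p = 0.0726).

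At day 2, 6556 genes changed, 3200 higher and 3356 lower in KO, of which 568 and 713 by at least 2-fold. The groups did not overlap in 61.3% of the tested genes, where chance gives 10%. Against a 1.5-fold change 847 genes passed. No gene list passed in this or any other comparison when the correlation between its genes was estimated from the data.

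KO and control were compared in the same way at day 4. Genes of the integrated stress response rose in 18 of 20 cases and fell in 0, with 18 and 0 adjusted over the list alone, and Ddit4 and Ppp1r15a did not pass (camera adjusted p = 2.86e-12; adjusted p = 0.209 with an estimated correlation). Pck2, a mitochondrial phosphoenolpyruvate carboxykinase, was 92.0 ± 12.5 CPM in KO and 15.4 ± 1.19 CPM in control, a rise of 2.58 ± 0.24 (edgeR adjusted p = 8.07e-07). Chac1 was 37.0 ± 6.65 and 6.49 ± 0.674 CPM, and Nupr1 was 27.8 ± 2.69 and 5.35 ± 0.635 CPM. Slc7a5, an amino acid transporter, rose by 1.37 ± 0.09 and Trib3, a pseudokinase, by 1.88 ± 0.14. Atf4, the factor at the centre of this response, was 254 ± 28.5 CPM in KO and 140 ± 11.5 CPM in control.

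Glycolysis genes were lower in KO at day 4 in 18 of 19 cases and higher in 0, with 18 and 0 adjusted over the list alone (camera adjusted p = 1.52e-10; adjusted p = 0.311 with an estimated correlation). Hk2 alone did not pass, at -0.16 ± 0.10 (edgeR adjusted p = 0.239), and it passed without control replicate 1, at -0.29. Slc16a3, a lactate exporter, was 9.46 ± 2.55 CPM in KO and 131 ± 57.6 CPM in control, and Tpi1, triosephosphate isomerase, was 67.1 ± 9.65 and 368 ± 114 CPM. Aldoc, an aldolase, fell by 3.39 ± 0.39. The control libraries of day 4 varied in these genes more than the KO libraries did, as the SDs show. Several of the largest decreases lay outside the list: Ndufa4l2, a mitochondrial protein gene, fell by 4.22 ± 0.62, Pygl, a glycogen phosphorylase, by 3.41 ± 0.25, Adm, which encodes adrenomedullin, by 3.39 ± 0.51, and Cd22, a sialic acid-binding lectin, by 3.45 ± 0.31. Bnip3, a mitophagy receptor on chromosome 7 at 138890836 to 138909519, minus strand, was 15.1 ± 3.17 CPM in KO and 152 ± 73.4 CPM in control.

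**Figure D2:**
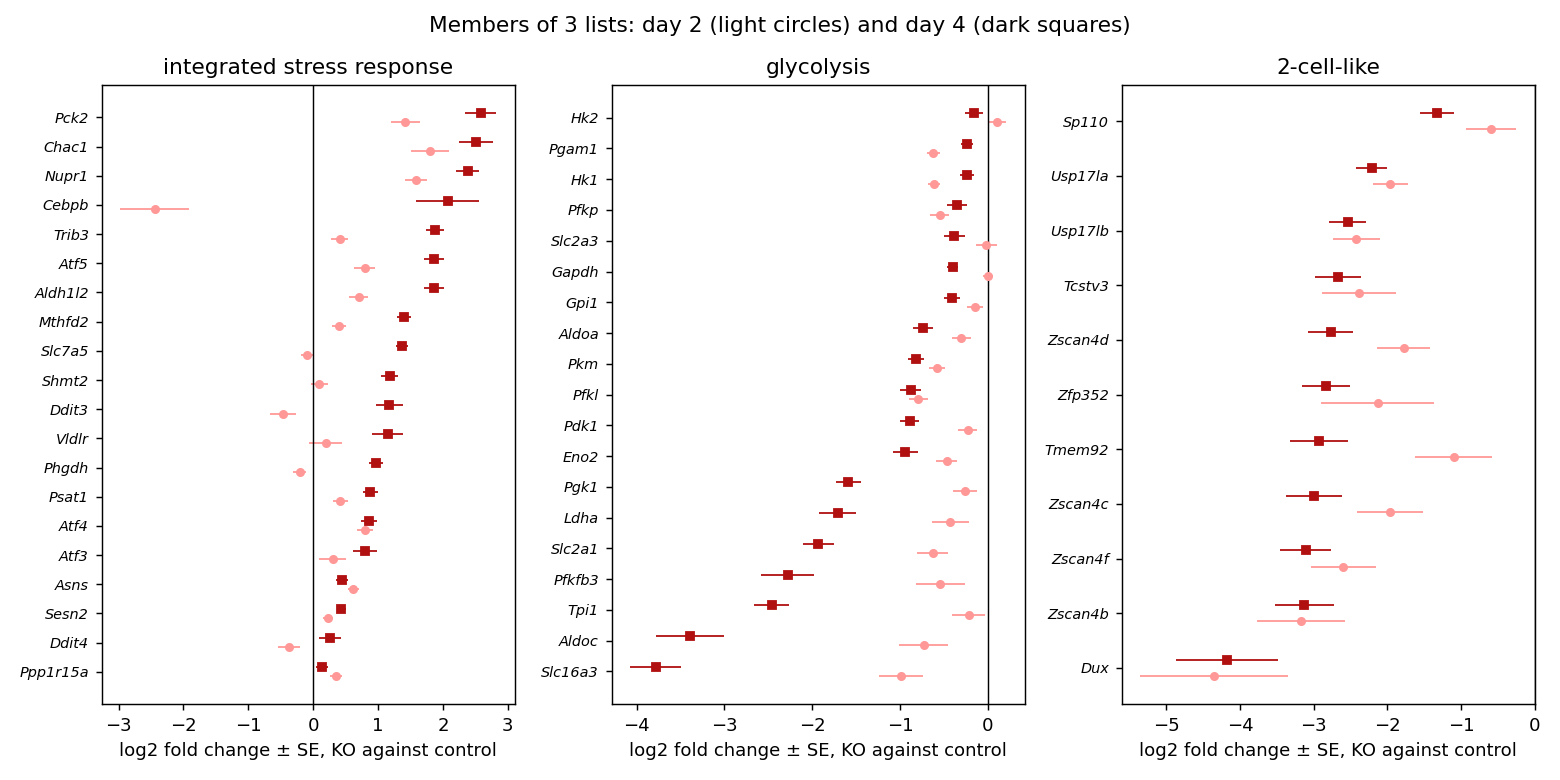
Log2 fold change ± standard error, Atg7 KO against control with 3 libraries each, of the tested members of 3 gene lists at day 2 (light circles) and day 4 (dark squares). Slc16a3 was at -3.78 and Pck2 at 2.58 at day 4, and the 11 2-cell-like genes were lower at day 4.

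Naive genes were higher in KO at day 4 in 14 of 20 cases and lower in 1, Dppa3, with 14 and 1 adjusted over the list alone (camera adjusted p = 1.14e-05; adjusted p = 0.0643 with an estimated correlation). Nanog was 682 ± 95.1 CPM in KO and 413 ± 4.27 CPM in control, a rise of 0.72 ± 0.10 (edgeR adjusted p = 3.37e-05). Klf4 was 92.7 ± 12.8 and 43.0 ± 2.54 CPM, Tfcp2l1 was 296 ± 29.2 and 167 ± 7.34 CPM, and Tbx3, a T-box factor, was 336 ± 19.8 and 173 ± 11.5 CPM. These levels in KO were still below those of ESCs. Dppa3, which encodes a maternal factor that protects DNA methylation marks, lies on chromosome 6 at 122626410 to 122630272 and fell from 39.2 ± 5.79 CPM in control to 4.37 ± 0.921 CPM in KO. In the general pluripotency list 8 of 16 genes rose and 2 fell (Dppa2 and Epcam), with 8 and 2 adjusted over the list alone (camera adjusted p = 0.151). Dppa2 did not pass without KO replicate 1 (-0.37) or 2 (-0.35) or without control replicate 1 (-0.36). Pou5f1 rose by 0.42 ± 0.05, Sox2 by 0.32 ± 0.06 and Gdf3, a TGF-beta ligand, by 1.09 ± 0.12.

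The formative list was divided at day 4, with 5 of 19 genes higher (Fgf5, Dnmt3a, Zic2, Zic5 and Sfrp2) and 4 lower (Otx2, Pou3f1, Dusp6 and Grhl2), and 5 and 5 adjusted over the list alone (camera adjusted p = 0.897). Dusp6 was 153 ± 12.2 CPM in KO and 326 ± 26.9 CPM in control. Pou3f1 fell by 1.01 ± 0.23 and Dnmt3a rose by 0.31 ± 0.07. Otx2 fell by 0.55 ± 0.15, and without control replicate 2 it was at -0.36 and did not pass. Fgf5 was 1.66 ± 0.387 CPM in KO and 0.640 ± 0.308 CPM in control, and it did not pass without control replicate 1 (1.36) or 3 (1.09) or without KO replicate 1 (1.24). Of the Nodal and Activin targets 8 of 11 rose and 0 fell, with 8 and 0 adjusted over the list alone (camera adjusted p = 0.0183; adjusted p = 0.241 with an estimated correlation). Egr1, an early response gene of ERK signalling on chromosome 18, was 3.60 ± 0.847 CPM in KO and 29.1 ± 1.61 CPM in control.

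All 11 2-cell-like genes were lower in KO at day 4, with 11 adjusted over the list alone (camera adjusted p = 9.29e-12; adjusted p = 0.193 with an estimated correlation). Zfp352 was 5.22 ± 0.259 CPM in KO and 37.2 ± 2.96 CPM in control, and Usp17lb, a ubiquitin protease gene, was 13.3 ± 0.907 and 77.2 ± 10.7 CPM. Germline genes fell in 8 of 16 cases and rose in 2 (Piwil2 and Rpl10l), with 8 and 3 adjusted over the list alone (camera adjusted p = 0.00829; adjusted p = 0.547 with an estimated correlation, and 0.533 with the collagen score). Piwil2 did not pass when any 1 of the 6 libraries was left out (0.21 to 0.30), nor Rpl10l in 4 of 6 refits (0.15 to 0.18). Trophoblast genes fell in 5 of 10 cases (Gata3, Gata2, Hand1, Krt7 and Peg10) and rose in 0, with 5 and 0 adjusted over the list alone (camera adjusted p = 0.0225; adjusted p = 0.193 with an estimated correlation), and Hand1 fell by 2.69 ± 0.40. Gata3 did not pass without KO replicate 3 (-0.52) and Peg10 without KO replicate 2 (-0.37), and the set did not pass with a stricter filter (0.16). Proteasome genes fell in 19 of 31 cases and rose in 2 (Psmc5 and Psmd3), with 19 and 2 adjusted over the list alone (camera adjusted p = 0.00669; adjusted p = 0.739 with an estimated correlation), and Psmc5 did not pass in 4 of 6 refits without 1 library (0.13 to 0.22). G2 and M phase genes fell in 13 of 24 cases and rose in 2 (Aurkb and Ube2c), with 15 and 4 adjusted over the list alone (camera adjusted p = 0.00226; adjusted p = 0.452 with an estimated correlation). The selective autophagy receptors rose in 4 of 15 cases (Calcoco1, Wdfy3, Fkbp8 and Phb2) and fell in 6, with 4 and 7 adjusted over the list alone (camera adjusted p = 0.132), and Sqstm1 fell by 0.48 ± 0.05. Of the 28 core autophagy genes 7 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.897), and Atg12 fell by 0.40 ± 0.07.

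Of the lists that passed at day 2, 3 did not at day 4. Targets of p53 had 1 higher and 2 lower of 19 (1 and 2 adjusted over the list alone; camera adjusted p = 0.683), cholesterol biosynthesis had 7 higher and 5 lower of 20 (7 and 5 adjusted over the list alone; camera adjusted p = 0.439), and the S phase had 6 higher and 4 lower of 22 (6 and 5 adjusted over the list alone; camera adjusted p = 0.683). With the collagen score the p53 targets passed upward at day 4, at 0.29. Conversely, at day 2 the proteasome had 5 higher and 7 lower of 31 (5 and 7 adjusted over the list alone; camera adjusted p = 0.262, and 0.0201 with the collagen score), and the Nodal and Activin targets had 5 higher and 3 lower of 11 (6 and 3 adjusted over the list alone; camera adjusted p = 0.262). In a test of the difference between days, cholesterol biosynthesis and the S phase differed, as given below. The p53 targets (camera adjusted p = 0.136), the proteasome (0.258) and the Nodal and Activin targets (0.751) did not, so a different effect by day was not shown for these.

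At day 4, 5903 genes changed, 3058 higher and 2845 lower in KO, or 2648 and 3308 with upper quartile scaling, so which direction held more genes is not settled. By at least 2-fold 218 were higher and 824 lower, and against a 1.5-fold change 614 passed. Groups without overlap made up 54.9% of the tested genes, where chance gives 10%. Single genes with large increases were Cox6a2, a cytochrome oxidase subunit of muscle, at 3.94 ± 0.37, and Ubap1l, at 3.38 ± 0.42. The increase of Mmp3, 4.57 ± 1.55, did not pass without KO replicate 3, at 3.13, nor without control replicate 1, 2 or 3, at 3.98, 4.79 and 5.23. Col1a1 was 38.2 ± 3.42 CPM in KO and 12.1 ± 0.999 CPM in control.

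**Figure D3:**
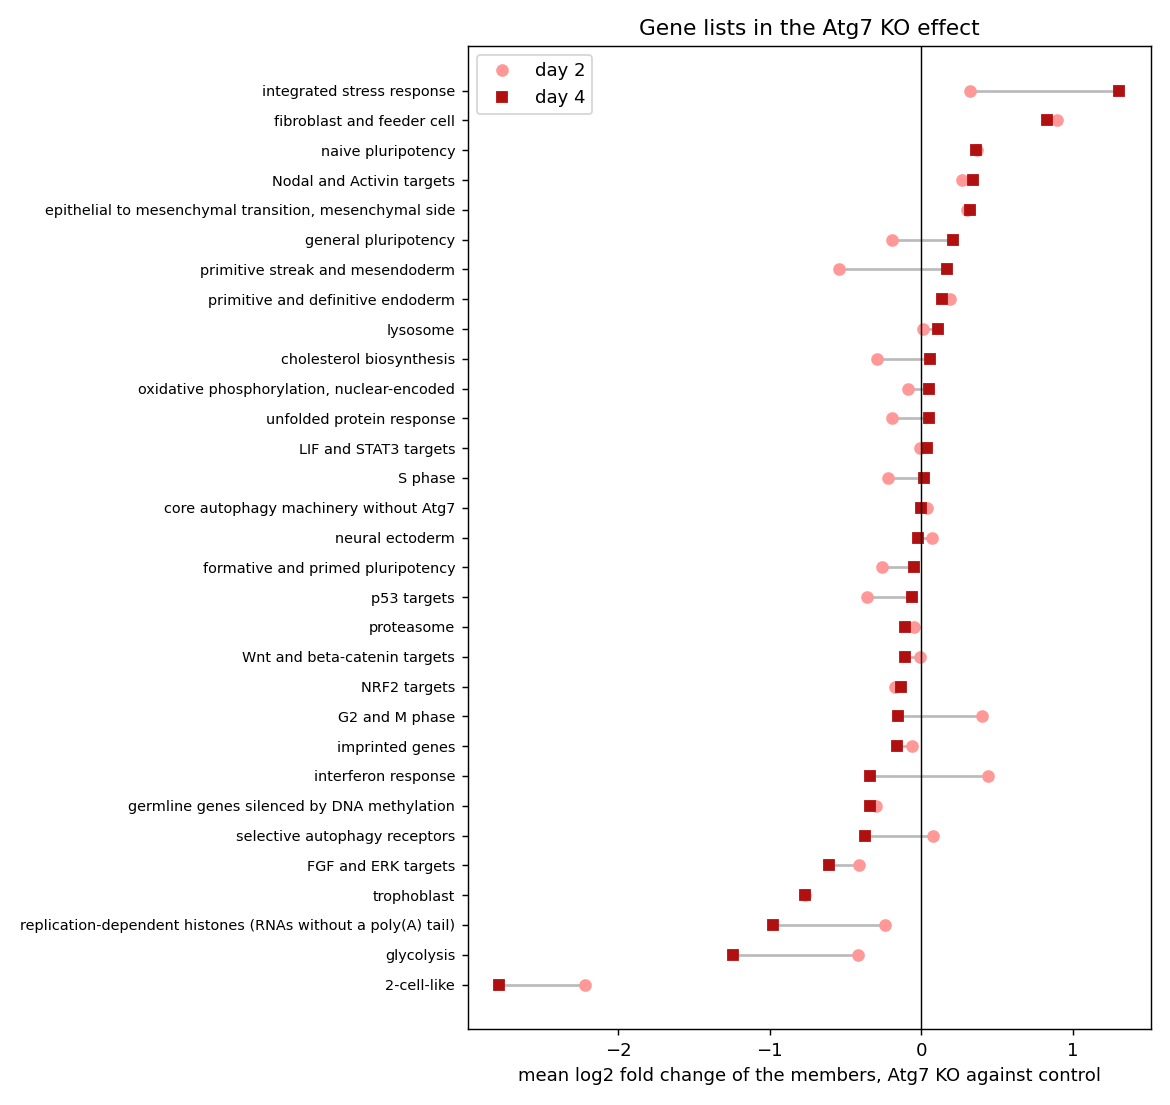
Mean log2 fold change of the tested members of 31 gene lists, Atg7 KO against control, at day 2 (circles) and day 4 (squares), in the order of the day 4 value. The 2-cell-like list was at -2.22 and -2.79, glycolysis at -0.42 and -1.24, and the integrated stress response at 0.32 and 1.31.

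Several lists did not pass at either day in the KO. The endoderm list had 7 higher and 3 lower of 16 at day 2 (camera adjusted p = 0.351) and 5 higher and 0 lower at day 4 (0.14), and the primitive streak list had 2 higher and 5 lower of 10 at day 2 (camera adjusted p = 0.164) and 1 higher and 0 lower at day 4 (0.727). The neural ectoderm list had 4 higher and 3 lower of 10 at day 2 (camera adjusted p = 0.515) and 3 higher and 1 lower at day 4 (0.683), and the fibroblast list had 6 higher and 0 lower of 19 at day 2 (camera adjusted p = 0.073) and 2 higher and 0 lower at day 4 (0.231). The collagen score was still higher in every KO library than in every control library of its day. It was 6.51 to 7.49 against 5.41 to 5.69 at day 2, and 4.28 to 4.74 against 2.79 to 3.04 at day 4. Unequal fibroblast RNA would thus go along with the KO, and the groups alone cannot tell it from an effect of the KO. Lysosome genes had 6 higher and 8 lower of 27 at day 2 (camera adjusted p = 0.779) and 9 higher and 6 lower at day 4 (0.231), and NRF2 targets had 2 higher and 7 lower of 16 at day 2 (camera adjusted p = 0.246) and 2 higher and 8 lower at day 4 (0.0539). Genes of the unfolded protein response had 1 higher and 6 lower of 16 at day 2 (camera adjusted p = 0.073) and 4 higher and 4 lower at day 4 (0.683), and nuclear-encoded genes of oxidative phosphorylation had 2 higher and 9 lower of 30 at day 2 (camera adjusted p = 0.13) and 11 higher and 6 lower at day 4 (0.238). FGF and ERK targets had 2 higher and 7 lower of 17 at day 2 (camera adjusted p = 0.13) and 2 higher and 5 lower at day 4 (0.156), and Wnt targets had 3 higher and 4 lower of 13 at day 2 (camera adjusted p = 0.964) and 2 higher and 1 lower at day 4 (0.897). LIF and STAT3 targets had 2 higher and 3 lower of 15 at day 2 (camera adjusted p = 0.953) and 7 higher and 3 lower at day 4 (0.0539), and mesenchymal genes had 4 higher and 1 lower of 17 at day 2 (camera adjusted p = 0.262) and 5 higher and 2 lower at day 4 (0.151). Interferon response genes had 5 higher and 0 lower of 16 at day 2 (camera adjusted p = 0.262) and 3 higher and 3 lower at day 4 (0.439), and imprinted genes had 6 higher and 8 lower of 23 at day 2 (camera adjusted p = 0.682) and 4 higher and 8 lower at day 4 (0.231). Replication-dependent histone genes had 0 higher and 0 lower of 9 at day 2 (camera adjusted p = 0.794) and 0 higher and 4 lower at day 4 (0.113). Adjusted over the list alone, the counts were the same except for the primitive streak list (2 and 5 at day 2, 0 and 0 at day 4), the neural ectoderm list (5 and 4 at day 2, 3 and 1 at day 4), the fibroblast list (4 and 0 at day 2, 2 and 0 at day 4), lysosome genes (6 and 8 at day 2, 10 and 6 at day 4), NRF2 targets (3 and 8 at day 2, 2 and 8 at day 4), genes of the unfolded protein response (1 and 6 at day 2, 4 and 5 at day 4), nuclear-encoded genes of oxidative phosphorylation (2 and 9 at day 2, 12 and 7 at day 4), LIF and STAT3 targets (1 and 3 at day 2, 7 and 3 at day 4), mesenchymal genes (3 and 1 at day 2, 5 and 2 at day 4), imprinted genes (6 and 8 at day 2, 4 and 9 at day 4), and replication-dependent histone genes (0 and 0 at day 2, 0 and 5 at day 4). With 1 library left out, some of these lists passed: at day 2 the unfolded protein response without control replicate 3 (mean -0.23) or KO replicate 2 (-0.21) and the fibroblast list without KO replicate 1 (1.08). At day 4 the endoderm list passed without control replicate 1 (0.21), NRF2 targets without control replicate 2 or KO replicate 1 or 3 (-0.16 to -0.12), LIF and STAT3 targets without control replicate 2 or any 1 of the KO replicates (0.04 to 0.10), and the histones without control replicate 2 (-1.23) or KO replicate 3 (-1.24). With the collagen score FGF and ERK targets passed at both days (-0.90 and -1.16), and at day 4 so did the endoderm list (0.29), NRF2 targets (-0.21) and imprinted genes (-0.52). NRF2 targets at day 4 also passed with RLE factors (-0.14), a stricter filter (-0.27) and a replicate block (-0.13), LIF and STAT3 targets at day 4 with RLE factors (0.04), and the fibroblast list at day 2 with a replicate block (0.91).

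Whether the KO effect differed between day 4 and day 2 was tested as an interaction, and it differed for many of the genes above. The difference was 1.46 ± 0.12 for Slc7a5 and 4.51 ± 0.72 for Cebpb, a bZIP factor that was lower in KO at day 2 and higher at day 4. For Bnip3 it was -3.55 ± 0.38, for Slc16a3 -2.78 ± 0.38, for Cd22 -3.93 ± 0.50 and for Pygl -3.31 ± 0.36. Hrk, an activator of apoptosis, was 1.25 ± 0.162 CPM in KO at day 2 and 6.46 ± 0.827 CPM at day 4, with a difference of 3.05 ± 0.40. Dppa3 differed by -2.65 ± 0.22, Otx2 by -1.88 ± 0.22 and Utf1 by 2.05 ± 0.23. Among naive genes Tbx3 differed by 1.03 ± 0.09 and Klf4 by 0.88 ± 0.15. Nanog differed by -0.40 ± 0.14 (edgeR adjusted p = 0.0323), but this call was lost in 8 of 12 refits that left out 1 library, where the value was between -0.41 and -0.30. The effect on the 2-cell-like list did not differ as a set (camera adjusted p = 0.412), and 1 of its 11 genes, Tmem92, differed (0 adjusted over the list alone), a call lost in 11 of 12 refits (-1.96 to -1.65).

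By list, the difference was positive for the integrated stress response, with 14 of 20 genes past the test upward and 0 downward (14 and 0 adjusted over the list alone; camera adjusted p = 0.000155; adjusted p = 0.687 with an estimated correlation). It was negative for glycolysis, with 10 of 19 downward and 2 upward, Hk1 and Pgam1 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00519; adjusted p = 0.883 with an estimated correlation). The G2 and M phase list had 20 of 24 downward and 0 upward (20 and 0 adjusted over the list alone; camera adjusted p = 1.22e-11; adjusted p = 0.256 with an estimated correlation), with Kif11 at -0.98 ± 0.08. The S phase list had 11 of 22 upward and 0 downward (13 and 1 adjusted over the list alone; camera adjusted p = 0.0035; adjusted p = 0.630 with an estimated correlation), and cholesterol biosynthesis 11 of 20 upward and 0 downward (12 and 0 adjusted over the list alone; camera adjusted p = 0.00024; adjusted p = 0.630 with an estimated correlation). General pluripotency had 7 of 16 upward and 1 downward, L1td1 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0212; adjusted p = 0.747 with an estimated correlation). With a stricter filter the S phase (0.0645) and general pluripotency (0.0889) sets did not pass.

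Over all genes, the effect differed for 5674, with 2919 differences positive and 2755 negative (2527 and 3095 with upper quartile scaling), and for 846 against a 1.5-fold difference. Of the genes tested at both days, 849 were higher in KO at both and 878 lower at both, where independent lists would give 623.4 and 608.3. Another 473 were higher at day 2 and lower at day 4, and 645 were lower at day 2 and higher at day 4, against 580 and 653.8 for independent lists. Across the 15696 genes, which are not independent replicates, the effects of the days correlated with Pearson's r = 0.29 and Spearman's rho = 0.18.

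The KO cells were also followed from day 2 to day 4. The 2-cell-like genes rose in 10 of 11 cases, all but Dux (10 adjusted over the list alone; camera adjusted p = 0.00117; adjusted p = 0.511 with an estimated correlation, and 0.157 with the collagen score), as Zfp352 did, by 4.95 ± 0.57, with 7.46 without KO day 2 replicate 3. The germline list rose in 16 of 16 cases (16 adjusted over the list alone; camera adjusted p = 1.26e-06; adjusted p = 0.356 with an estimated correlation). In control over these days 11 of the 11 2-cell-like genes rose (11 adjusted over the list alone; camera adjusted p = 4.97e-06; adjusted p = 0.556 with an estimated correlation) and 15 of the 16 germline genes (15 adjusted over the list alone; camera adjusted p = 1.41e-06; adjusted p = 0.395 with an estimated correlation). The means were 2.71 in KO and 3.28 in control for the 2-cell-like list, and 1.12 and 1.15 for the germline list. In the test of the difference the germline set did not pass (camera adjusted p = 0.882), but 3 of its genes were past the test upward and 4 downward (3 and 4 adjusted over the list alone). Dnmt3a rose by 1.91 ± 0.08 and Dnmt3b by 1.67 ± 0.20, while Nanog fell by 0.77 ± 0.10 and Spic by 4.3 ± 0.29. Esrrb rose by 0.65 ± 0.07 and Zfp57, which protects imprints, by 0.77 ± 0.09. Of the 20 naive genes 12 fell and 8 rose (12 and 8 adjusted over the list alone; camera adjusted p = 0.193). In all 9922 genes changed from day 2 to day 4 in KO, 4900 higher and 5022 lower, or 3655 against a 1.5-fold change. Both in control and in KO 3446 genes rose and 3632 fell.

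Last, the genes that were higher or lower in control cells than in ESCs were tested as sets in the KO effect, each set taken from a time comparison that shared no library with the effect. The 2990 genes that rose at least 2-fold from day 0 to day 4 were on average lower in KO at day 2, with a mean log2 fold change of -0.248, 836 lower and 384 higher (camera adjusted p = 0.00665; adjusted p = 0.111 with an estimated correlation). Without a fold minimum the mean was -0.11 and the set did not pass (camera adjusted p = 0.451), and with a stricter filter it was -0.16. The 1869 genes that fell had a mean of 0.112 at day 2, with 416 higher and 326 lower (camera adjusted p = 0.21), and of 0.05 without a fold minimum. At day 4, the 2686 genes that had risen from day 0 to day 2 had a mean of -0.321 in the KO effect, with 717 lower and 227 higher (camera adjusted p = 1.29e-05; adjusted p = 0.0907 with an estimated correlation), and of -0.17 without a fold minimum. The 1764 that had fallen had a mean of 0.05, with 368 higher and 190 lower (camera adjusted p = 0.0465; adjusted p = 0.506 with an estimated correlation), and this call was lost in 4 of 12 refits that left out 1 library, where the mean was between 0.02 and 0.07. Its mean was 0.08 without a fold minimum and 0.14 with a stricter filter. All 4 sets rest on the ESC libraries, which held unequal collagen RNA and an Hprt level unlike that of the later cells. The collagen score was also higher in every KO library than in every control library of its day. The sets were not refitted with that score, so the share of fibroblast RNA in their shifts was not tested.

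**Figure D4:**
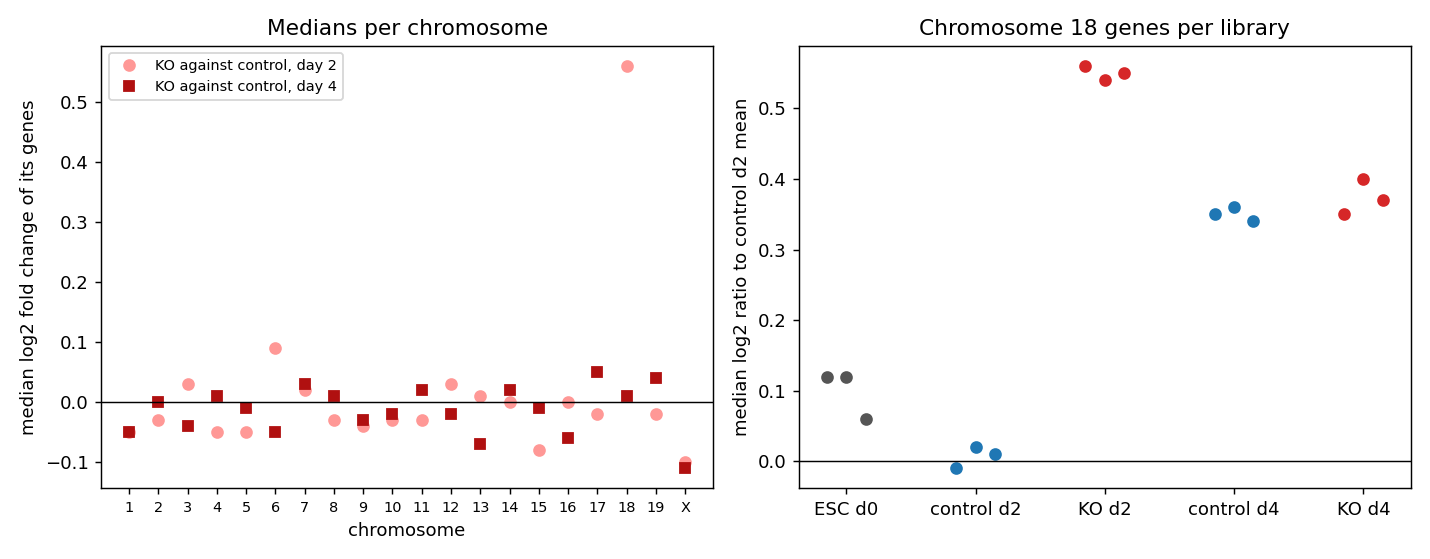
Left, median log2 fold change of the genes of each autosome and of X, Atg7 KO against control, at day 2 (circles) and day 4 (squares). Chromosome Y, with 8 tested genes, is not drawn and had medians of 0.8 at day 2 and -0.04 at day 4. Right, median log2 ratio of the chromosome 18 genes to the control day 2 mean in each library, where KO day 2 libraries lie between 0.54 and 0.56.

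**Figure D5:**
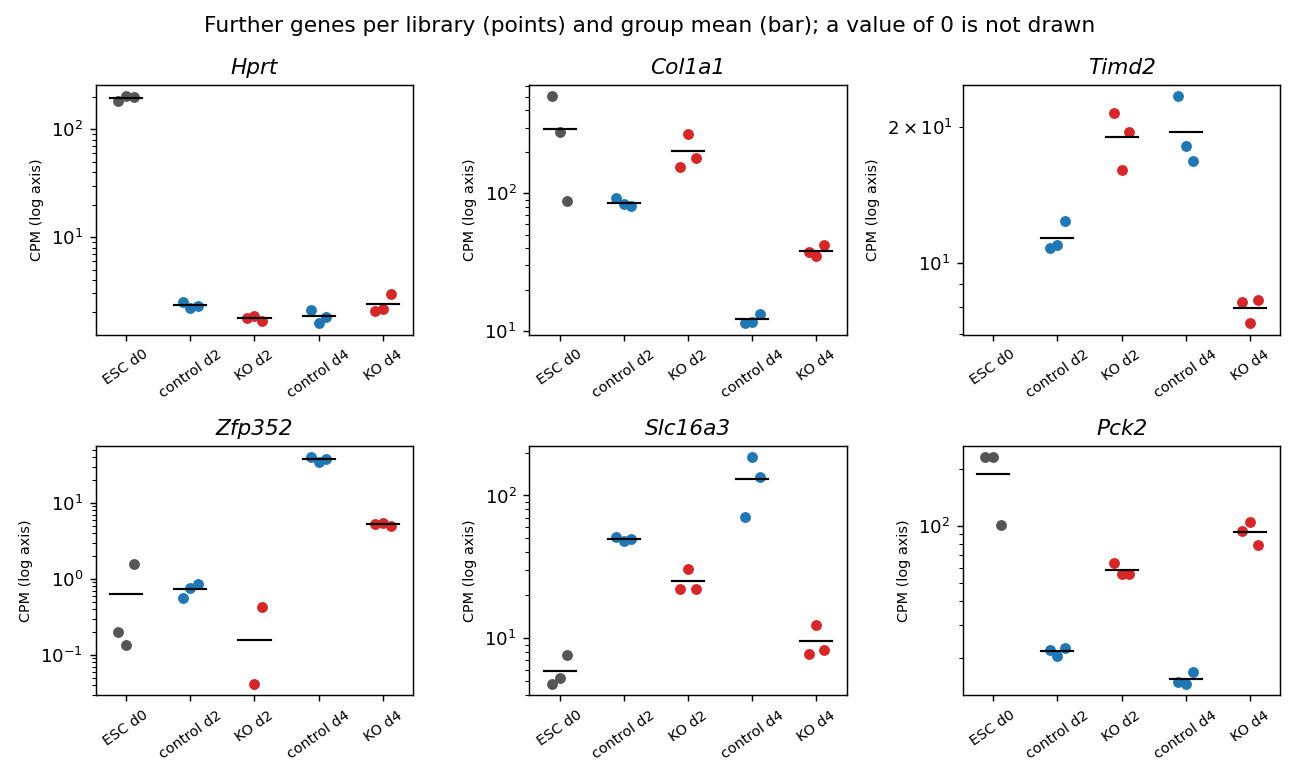
CPM on a log axis of 6 further genes in each library (points) and the mean of each group (bar), with values of 0 not drawn. Hprt was 195 ± 11.2 CPM in ESCs and 2.34 ± 0.152 CPM in control at day 2, and Timd2 had 0 counts in ESCs.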

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

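The test of the difference between days and the other splits of the samples were fixed in advance, and the genes named below follow the report. What drew attention to each result in this part is that its Atg7 KO effect differed between day 4 and day 2 in a test of that difference itself. This was so for 5674 genes. By list, the mean log2 difference was 0.98 for the integrated stress response, 0.39 for general pluripotency, 0.35 for cholesterol biosynthesis, 0.24 for S phase, -0.56 for G2 and M phase and -0.82 for glycolysis.

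Among named genes the log2 difference was positive for Cebpb (4.51), Hrk (3.05), Ubap1l (2.48), Utf1 (2.05), Galnt3 (1.85), Cdcp1 (1.63), Trib3 (1.48), Slc7a5 (1.46), Map1lc3a (1.35), Zfp57 (1.28), Ung (1.27), Grb10 (1.24), Pck2 (1.15), Klf5 (1.10), Tbx3 (1.03), Uqcrc1 (0.91), Klf4 (0.88), Peg10 (0.83), Sfrp2 (0.82), Psmd3 (0.71), Gata6 (0.71), Vegfa (0.67), Zic5 (0.66), Dnmt3a (0.64), Tfcp2l1 (0.63), Fkbp8 (0.57), Wdfy3 (0.52), Esrrb (0.44), Pou5f1 (0.44), Phb2 (0.42), Pgam1 (0.38) and Hk1 (0.37). It was negative for Cd22 (-3.93), Bnip3 (-3.55), Pygl (-3.31), Egr1 (-3.02), Adm (-2.99), Spic (-2.80), Slc16a3 (-2.78), Aldoc (-2.66), Dppa3 (-2.65), Tpi1 (-2.23), Timd2 (-2.03), Glcci1 (-2), Otx2 (-1.88), Lefty1 (-1.60), L1td1 (-1.06), Atg12 (-1.03), Kif11 (-0.98), Bnip3l (-0.92), Sall2 (-0.91), Tfap2c (-0.87), Fbxo15 (-0.86), Tax1bp1 (-0.80), Sqstm1 (-0.72), Ndufa4 (-0.70) and Nbr1 (-0.39). Of these, Egr1, Atg12, Fbxo15 and Gata6, and Sall3 below, lie on chromosome 18, whose 401 genes had a median difference of -0.59, where the other autosomes were between -0.18 and 0.07. A difference near that median cannot be told from the shift of the chromosome.

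For 13 further named genes the difference passed with all libraries but not in every one of the 12 refits that left out 1 library. Those lost in 1 refit were Cox6a2 (3.12, and 2.64 without control day 2 replicate 1) and Ndufa4l2 (-2.91, and -2.27 without KO day 2 replicate 2). Lost in 2 refits were Nupr1 (0.80, and 0.67 and 0.70 without control day 2 replicate 2 and control day 4 replicate 1), Grhl2 (0.43, and 0.39 and 0.38 without KO day 2 replicate 1 and control day 4 replicate 3), Hprt (0.75, and 0.58 and 0.66 without KO day 4 replicate 3 and control day 4 replicate 2) and Piwil2 (0.43, and 0.38 without KO day 2 replicate 1 or control day 4 replicate 1). Lost in more were Tead2 (0.22, lost in 4), Sall3 (-0.89, lost in 5), Zic2 (0.48, lost in 7), Nanog (-0.40, lost in 8), Ddit4 (0.65, lost in 10), Tmem92 (-1.83, lost in 11) and Dnmt3b (0.79, lost in 12).

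The comparisons were repeated with the libraries of the groups compared split in other ways. Each comparison of 3 with 3 libraries has 10 splits, the real one among them, which is too few for a share under 0.05. The other splits mix the groups compared, so the difference between these adds to the scatter and is diluted. A low gene count or a small mean shift in them is therefore no support for the real split. In 1 of 10 splits, the real one, as many genes changed as reported: 11072, 10741 and 11257 for control day 2 against ESCs, day 4 against day 2 and day 4 against ESCs, 6556 and 5903 for KO against control at day 2 and day 4, and 9922 for KO day 4 against KO day 2, where the highest other split gave 0 each time. For the lists, as many or more were called in 5 of 10 splits for control day 2 against ESCs (11 called, highest other 18), 9 for day 4 against day 2 (7, highest other 10), 5 for day 4 against ESCs (12, highest other 15), 2 for KO against control at day 2 (10, highest other 12), 2 at day 4 (9, highest other 9) and 3 for KO day 4 against KO day 2 (10, highest other 12). The number of lists called therefore says little. For the time-course sets 1 of 10 splits, the real one, reached the absolute mean shift reported: 0.248, 0.112, 0.321 and 0.05 against 0.149, 0.065, 0.132 and 0.044 in the highest other split.

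For the difference between days 100 splits were run, the real one and others drawn at random from all that exist. As many genes as the 5674 were called in 2 of them, the real one and the one that exchanges KO and control at day 4, which tests the sum of both effects and called 6799. The other splits mix KO and control libraries within a group, so that the KO effect itself adds to the scatter inside the groups, and the share is no test of the gene count. As many lists as the 6 called were called in 58 of 100 splits, with a highest other of 15.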

How the results depend on the processing

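Of the counts of changed genes, all stayed within 1.5 times their value with RLE or upper quartile scaling, without a filter or with a stricter one, with DESeq2, with only the groups compared, and, chosen after the data were seen, with 13 libraries. Dropping the 401 chromosome 18 genes from the main fit, also chosen after the data were seen, left 15696 genes nearly complete. It could hardly move a count and is no test of the counts. Scaling shifted the median of all genes by less than 0.1 and turned 0 called lists. With RLE or upper quartile scaling, or both, the direction that held more genes turned in each comparison but control day 4 against ESCs: with upper quartile scaling 2648 were higher and 3308 lower in KO at day 4, and 2527 differences between days were positive and 3095 negative. Against a 1.5-fold change, which by construction asks for larger effects, the counts were 5273 (control day 2 against ESCs), 4794 (day 4 against day 2), 5792 (day 4 against ESCs), 847 and 614 (KO at day 2 and day 4), 3655 (KO day 4 against KO day 2) and 846 (difference between days). With an estimated correlation 0 lists passed in each of the 7 comparisons, and of the time-course sets those of -0.25 (risen, day 2), -0.32 (risen, day 4) and 0.05 (fallen, day 4) no longer passed. Without a fold minimum the risen set at day 2 was at -0.11 and did not pass, the fallen set at day 2 was at 0.05, the risen set at day 4 at -0.17 and the fallen set at day 4 at 0.08. With a stricter filter the risen set at day 2 was at -0.16 and the fallen set at day 4 at 0.14. The cause was not tested.

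With the feeder score as a covariate, chosen after the data were seen, 7113 genes changed between ESCs and control at day 4, and 13 lists (control day 4 against day 2) and 14 (KO at day 4) passed. The fibroblast list reversed to 1.08, 1.40 and 2.48 in the control comparisons (day 2 against ESCs, day 4 against day 2, day 4 against ESCs), to -0.44 and -0.62 in KO at day 2 and day 4, and to 1.21 from day 2 to day 4 in KO. The score is built from 3 genes of that list. The p53 targets reversed to -0.58 (control day 4 against ESCs), 0.29 (KO at day 4) and -0.40 (KO day 4 against KO day 2), and the cause was not tested.

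Leaving out 1 library gave between 10541 and 11804 genes (control day 2 against ESCs), 10024 and 10187 (day 4 against day 2), 10784 and 11891 (day 4 against ESCs), 5112 and 5626 (KO at day 2), 4790 and 5054 (KO at day 4), 9154 and 9301 (KO day 4 against KO day 2) and 4832 and 5132 (difference between days). In the same order 10 to 15, 7 to 8, 12 to 14, 9 to 11, 9 to 12, 10 to 11 and 6 to 7 lists passed. The time-course sets had means from -0.30 to -0.19 (risen, day 2), 0.09 to 0.14 (fallen, day 2), -0.34 to -0.29 (risen, day 4) and 0.02 to 0.07 (fallen, day 4, lost in 4 of 12 refits).

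With the replicate number as a block the counts were 10982, 10669, 11185, 6393, 5759, 9825 and 5518, in the order control day 2 against ESCs, day 4 against day 2, day 4 against ESCs, KO at day 2, KO at day 4, KO day 4 against KO day 2, and difference between days. Deviations from the group mean correlated between libraries of equal number in different groups with r from -0.095 to 0.081 over 30 pairs, none of them over 0.1, across genes that are not independent replicates. No strong pairing showed. Of the 15 libraries, 8 correlated best with a library of their own number in another group, so a weak pairing is not excluded.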

Other observations

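The HIF list and all tests in this part that use it, the tests on Hprt and the test of windows on chromosome 18 were chosen after the result was seen. Between ESCs at day 0 and control cells at day 4, 26 of 30 nuclear-encoded genes of oxidative phosphorylation fell and 2 rose, Ndufa4 and Cycs (26 and 2 adjusted over the list alone; camera adjusted p = 1.06e-08; adjusted p = 0.285 with an estimated correlation). Ndufa4, at 0.32, and Cycs, at 0.45, lie on chromosome 6, whose genes had a median of 0.44 in this comparison. Their rises cannot be told from the shift of that chromosome. Uqcrc1, a subunit of complex III, fell by 1.46 ± 0.05. Proteasome genes fell in 24 of 31 cases, with Psmb5, a catalytic subunit, down by 1.59 ± 0.08, and rose in 2 (24 and 2 adjusted over the list alone; camera adjusted p = 1.74e-05; adjusted p = 0.371 with an estimated correlation), and with the feeder score as a covariate that call was lost (mean -0.17). S phase genes fell in 19 of 22 cases and rose in 1 (19 and 2 adjusted over the list alone; camera adjusted p = 3.89e-06; adjusted p = 0.249 with an estimated correlation) and cholesterol biosynthesis genes fell in 17 of 20 and rose in 2 (17 and 2 adjusted over the list alone; camera adjusted p = 1e-04; adjusted p = 0.285 with an estimated correlation). Neither the cholesterol nor the proteasome list moved 1 way throughout. Of the cholesterol genes 15 rose and 2 fell up to day 2 (camera adjusted p = 0.000738; 0.371 with an estimated correlation), and 20 fell from day 2 to day 4 in control (camera adjusted p = 3.89e-10; 0.223 with an estimated correlation). Of the proteasome genes 28 fell and 0 rose up to day 2 (camera adjusted p = 2.59e-09; 0.371 with an estimated correlation), and 18 rose and 9 fell after it (camera adjusted p = 0.0809). The counts adjusted over the list alone were the same. Imprinted genes rose in 15 of 23 cases and fell in 5 (15 and 5 adjusted over the list alone; camera adjusted p = 0.0159; adjusted p = 0.317 with an estimated correlation). Among them Mest, expressed from the paternal allele, rose by 3.27 ± 0.09 and Grb10, an adaptor of growth factor receptors, fell by 3.19 ± 0.09. LIF and STAT3 targets fell in 10 of 15 cases and rose in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.000696; adjusted p = 0.29 with an estimated correlation), a call lost with the feeder score (mean -0.42).

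In KO cells from day 2 to day 4, 15 of 28 core autophagy genes fell and 4 rose (15 and 4 adjusted over the list alone; camera adjusted p = 0.00908; adjusted p = 0.356 with an estimated correlation), and 18 of 20 genes of the integrated stress response rose (18 adjusted over the list alone; camera adjusted p = 9.1e-06; adjusted p = 0.451 with an estimated correlation). Cholesterol biosynthesis genes fell in 19 of 20 cases (20 adjusted over the list alone; camera adjusted p = 4.47e-08; adjusted p = 0.356 with an estimated correlation), and FGF and ERK targets rose in 14 of 17 and fell in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.000167; adjusted p = 0.511 with an estimated correlation). In control over the same days 15 core autophagy genes fell and 6 rose (15 and 6 adjusted over the list alone; camera adjusted p = 0.081, past the test without chromosome 18 genes and with the feeder score, at means of -0.31 and -0.33). FGF and ERK targets rose there in 13 cases and fell in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.000628; 0.648 with an estimated correlation), and the cholesterol genes fell as given above. The stress response genes rose in 9 cases and fell in 5 (9 and 5 adjusted over the list alone; camera adjusted p = 0.658), and that set passed with the feeder score (mean 0.46). In the test of the difference between KO and control in these changes, the core autophagy (camera adjusted p = 0.662) and FGF and ERK (0.854) sets did not pass, but 7 core autophagy genes were past the test upward and 9 downward (7 and 10 adjusted over the list alone), and 4 FGF and ERK targets upward and 3 downward (4 and 3 adjusted over the list alone). The cholesterol and stress response sets differed, as given in the report, with means of -0.80 in KO and -1.15 in control and of 1.11 and 0.12.

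Chromosome 18 genes were higher in KO than in control at day 2 along the whole chromosome, with 257 of 401 genes higher and 10 lower, and the lowest median of a 10 Mb window was 0.48. Under a hypothesis of a gained chromosome 18 in the KO day 2 cells relative to the control day 2 cells, every window should lie near log2 of 1.5 (0.585). The window medians were between 0.48 and 0.69. The test only asked each window to exceed a limit set well below 0.585, after the median of the chromosome was seen. It therefore cannot tell a gain from any other even shift of the chromosome, and no DNA copy number was analysed here. Bias by GC content or gene length is excluded as the whole cause, since the median was 0.50 ± 0.02 after its removal, and so is feeder cell RNA, with a median of 0.56 with the feeder score as a covariate (both predictions written before the result was seen). Against the mean of control day 2, the medians were 0.54 to 0.56 in KO day 2 libraries, 0.34 to 0.36 in control day 4, 0.35 to 0.40 in KO day 4 and 0.06 to 0.12 in ESCs. The level thus differed between control day 2 and control day 4 as well, so the Atg7 genotype alone does not account for it. Chromosome 6, which holds Atg7, Nanog and Dppa3, also shifted with time. Its median was 0.39 from day 2 to day 4 in control, against 0.35 for chromosome 18, and 0.23 in KO. In KO against control it was 0.09 at day 2 and -0.05 at day 4.

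Hprt, a purine salvage gene of the X chromosome at 52988137 to 53021659 in which the E14TG2a line is known to carry a deletion, was 195 ± 11.2 CPM in ESCs and between 1.78 and 2.38 CPM in the means of the 4 later groups. Feeder cell RNA in the day 0 libraries is excluded as the source: Hprt in ESC replicate 3 was 1.10 times that in replicate 1, while Col1a1, Col1a2 and Col3a1 were 0.17, 0.14 and 0.07 times. Whether the day 0 libraries come from other cells than the rest was not settled. The test asked for genes at 0 counts on 1 side of day 0 and at least 5 CPM in every library of the other. It found 1 gene, Timd2, with 0 counts at day 0 and at least 5 CPM in every one of the 12 later libraries. This cannot decide, because other cells at day 0 and the transition itself would both give such genes, and Hprt was not at 0 counts later. Whole chromosomes also differed from the ESCs. The 605 genes of X had medians of 0.38 in control at day 2 and 0.46 at day 4, and the 8 tested genes of Y had -1.53 and -0.46. The autosomes other than 18 lay between -0.12 and 0.11 at day 2 and between -0.25 and 0.44 at day 4. These shifts were not tested as a sign of other cells. The Hprt level itself goes against the E14TG2a deletion in the ESCs, as far as 1 gene can tell, and the levels of the later groups do not. No biological explanation was tested.

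Targets of hypoxia-inducible factor (HIF) were lower in KO at day 4, with 14 of 16 genes lower and 1, Vegfa, higher by 0.80 ± 0.13 in a list written after their values were seen. A selection of genes by their result was tested on 21 further targets, whose values had not been looked at, with the prediction written before. Of these 10 were lower and 1 higher. They were lower as a set at the preset correlation (mean -0.42, camera p = 0.000419), but did not pass with an estimated correlation (camera p = 0.193). Whether selection is excluded as the whole cause thus depends on the correlation assumed. Removing a trend on GC content and gene length moved the median of all 37 targets from -0.88 to -0.83 ± 0.29, so the trend held little of the shift in these genes. The 37 include the 16 listed after their values were seen, so this excludes no bias for HIF targets in general. On the 21 alone the median went from -0.35 to -0.36 ± 0.18, and the question could not be decided. A culture difference between wells, such as in oxygen or cell density, could also give this and cannot be told apart from an effect of the KO: the gap between the lowest control and the highest KO library was 1.34, against a range of 1.13 and an SD of 0.60 within the control libraries. Control replicate 1, the lowest, was at 4.98 in the 21 further targets, against 4.88 to 4.95 in KO.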
